A study of Mus musculus with 4 samples.

How the data were processed

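Gene expression was measured by RNA sequencing in CAD cells (Cath.-a-differentiated), a mouse catecholaminergic neuronal cell line that takes on a neuron-like form when serum is withdrawn. Per the labels' protocols, cultures were kept without serum for 5 days and received for 24 h either a small-molecule inhibitor of the acetyl-CoA synthetase ACSS2 at 20 µM (called ACSS2i below) or its solvent DMSO. Each group had 2 libraries. Polyadenylated RNA was made into libraries with the ScriptSeq v2 kit, and the pooled libraries shared 1 lane of an Illumina NextSeq sequencer, per the labels' protocols. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

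The submitters' processing notes name bcl2fastq 02.14.01.07, STAR 2.3.0, Cufflinks 2.2.1 and Cuffdiff, and the genome build mm10. The annotation and the scaling between libraries were not given in the sources used here. The deposited table held 1 value per library for 24341 genes. The header names no unit, and the deposited values were taken as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, because the submitters' processing notes name Cufflinks and because the values behave like FPKM. The table is described as adjusted, and what the adjustment was is not stated in the sources used here. The lowest value in every library was 0.01, a floor. One gene, Sept7, held a failure mark in place of a value in ACSS2i replicate 2 and 127, 140.5 and 117 FPKM in DMSO replicate 1, DMSO replicate 2 and ACSS2i replicate 1. It was left out of the tests, which left 24340 genes.

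The depth of the libraries was read from the low values. Each relative depth was the most common ratio to DMSO replicate 1 among genes with values of at most 0.5 FPKM. Of these low genes, 2108 had scaled values that differed by at most 6 times. Among them 73.2% stood at whole multiples of each other within 1%, against 1.34% with random depths. The depths come from the same low values, so these shares do not test them independently. A depth wrong by a whole factor was not excluded. The relative depths were 1 for DMSO replicate 1, 0.292 for DMSO replicate 2, 0.675 for ACSS2i replicate 1 and 0.857 for ACSS2i replicate 2. With transcript lengths from GENCODE M21 for 197 genes with a single transcript, this came to a nominal 11600000, 3370000, 7810000 and 9920000 reads, rounded to 3 digits. A single read in a transcript of 3 kb was then worth 0.0288, 0.0988, 0.0427 and 0.0336 FPKM. Whole read counts could not be recovered for all genes, so a test on counts was not run.

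Tests were run on log2(FPKM + 1) for the 11486 genes with a mean of at least 1 FPKM over the 4 libraries. Log2 fold changes are on this scale, which understates the change of genes at low FPKM. The inhibitor libraries were compared with the DMSO libraries with limma 3.58.1 (R 4.3.3; moderated test with a mean-variance trend, two-sided), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors are limma's moderated ones. An exact permutation test of 2 against 2 libraries cannot go below 0.333. On simulated data with the same 11486 genes and 200 changed genes (20 runs), the test called 0.9% of the genes changed by log2 1 and 85.5% of those changed by log2 3, with 4.65 unchanged genes called per run.

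A total of 30 gene lists was fixed before the data were examined, along with the groups, the tests, the alternative settings and the rule for named genes. The lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 26 lists that qualified. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without reference to other genes, were the alternatives. In simulated lists for the same comparison, camera with the preset correlation called 0% of unshifted lists when genes were independent and 41.4% when they were correlated at 0.5. Camera with an estimated correlation called a list shifted by log2 1 in 0% of runs in both cases. In this design the preset test is thus open to false calls from correlated genes, and the estimated test can miss real shifts. Among the lists that passed the preset test, the correlation estimated from the data ran from -0.053 (postsynaptic) to 0.947 (cholesterol biosynthesis). It was 0.838 for G2 and mitosis and 0.609 for S phase, above the simulated 0.5. The rate of false calls at such correlations was not simulated.

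The genes named were the called genes with a mean of at least 5 FPKM and no overlap between groups (up to 12 in each direction), Acss2 with its paralogs Acss1 and Acss3, up to 4 members with the smallest unadjusted p of each fixed list, and Fos, Egr1, Syn1, Syp, Gap43, Tubb3, Map2, Th, Dbh, Hmgcs1 and Cdkn1a whatever their p. Some genes that this rule picks are not reported here. Any other gene named was chosen after its values were seen. Positions are from GENCODE M21, which is on the assembly GRCm38 that mm10 denotes. The alternative settings fixed in advance were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, each library left out in turn, other settings of the moderated test and its threshold, and the other list tests. After the data had been seen, 2 more were added: short RNA genes left out, and a correction of each library for transcript length and GC content. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.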

Results

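The data were 4 transcriptomes of serum-deprived CAD cells, 2 from cells given DMSO and 2 from cells given 20 µM of the ACSS2 inhibitor for 24 h. ACSS2 makes acetyl-CoA from acetate in the cytosol and the nucleus, and the comparison asked how the transcriptome of these neuron-like cells differed when the enzyme was inhibited. DMSO replicate 2 was the shallowest library, at a nominal 3370000 reads against 11600000 for DMSO replicate 1, 7810000 for ACSS2i replicate 1 and 9920000 for ACSS2i replicate 2. The FPKM values summed to 590549 and 590108 in the DMSO libraries and to 558458 and 675716 in the ACSS2i libraries. Short RNA genes took 7.35% and 11.6% of these sums in the DMSO libraries and 6.59% and 7.50% in the ACSS2i libraries. Across genes, which are not independent replicates, Pearson's r on log2(FPKM + 1) was 0.939 between the DMSO libraries, 0.921 between the ACSS2i libraries and 0.918 to 0.929 between libraries of different groups.

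The clearest difference between the groups was in genes of cell division. Both inhibitor libraries lay above both DMSO libraries in 30 of the 30 G2 and mitosis genes and in 24 of the 28 S phase genes. By camera with an estimated correlation both lists had adjusted p = 0.644. Mki67, the proliferation marker Ki-67, stood at 2.66 ± 2.09 FPKM in DMSO and 23.5 ± 1.89 FPKM in ACSS2i (SD, n = 2 each). By camera with the preset correlation the list of cytosolic heat shock genes was also higher, and those of voltage-gated ion channels and of endoplasmic reticulum chaperones were lower. With an estimated correlation these 3 had adjusted p = 0.644, 0.644 and 0.676, and 0 of their genes passed over the list alone. The ion channel call was lost without ACSS2i replicate 1 and the endoplasmic reticulum call without DMSO replicate 1. Single genes could rarely be separated from the spread between libraries: of 11486 genes tested with limma, 3 passed an adjusted p of 0.05, Snora64 and Snora16a higher and Mir7063 lower with the inhibitor. At an unadjusted p under 0.05 there were 378 genes higher and 421 lower, 799 in all. A share of 0.05 of the 11486 would pass by chance if p-values were uniform. The number fell without either DMSO library and rose without either ACSS2i library. Such fits take the spread from the intact pair alone, so they do not show what the omitted library added. The SD of the log2 differences within a pair was 0.638 for DMSO and 0.747 for ACSS2i. The smallest adjusted p outside short RNA genes was 0.259. The groups did not overlap in 4289 genes, 37.3% of those tested, where chance gives 33.3%. Of the 26 lists tested with camera at the preset correlation, 15 passed, 9 higher and 6 lower. With an estimated correlation 0 of the 26 passed, with adjusted p from 0.644 to 0.765 for the 15 lists, and 0 had an unadjusted p under 0.05. By fry 0 passed, with adjusted p from 0.342 to 0.775 for the 15 lists, and 3 of the 26 had an unadjusted p under 0.05. These 3 were the p53 targets (0.0273), the postsynaptic list (0.0364) and the presynaptic list (0.0488). The G2 and mitosis list had an unadjusted fry p of 0.0593 and the S phase list 0.0657. Only the lists of G2 and mitosis, S phase, and cytosolic heat shock passed the preset test whichever library was left out.

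**Figure D1:**
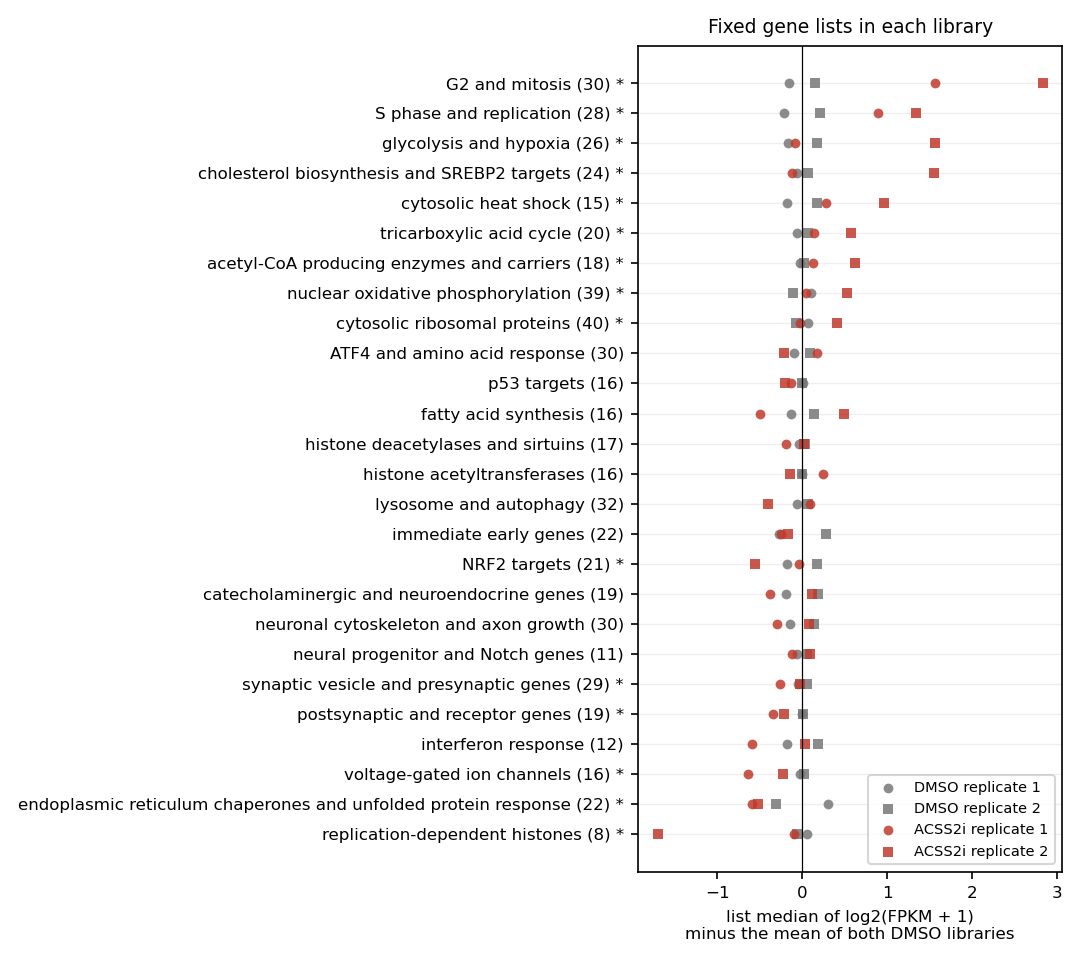
Median over each tested gene list of log2(FPKM + 1) minus the mean of the DMSO libraries (horizontal axis), for each of the 4 libraries (points), with the number of tested genes in parentheses and an asterisk at lists that passed camera with the preset correlation. The G2 and mitosis list lies at 1.57 and 2.84 in the inhibitor libraries, while cholesterol biosynthesis lies at -0.12 in ACSS2i replicate 1 and 1.55 in ACSS2i replicate 2.

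All 30 genes of the G2 and mitosis list were tested, and all 30 had higher values in both inhibitor libraries than in both DMSO libraries. The median log2 fold change was 2.16, with list medians of 1.57 in ACSS2i replicate 1 and 2.84 in ACSS2i replicate 2 relative to the DMSO mean. The median was 1.00 with a pseudocount of 5 and 3.35 with a pseudocount of 0.1. Adjusted over the list alone, 30 of the 30 rose, and 0 passed when adjusted over all genes. In the fit without an expression filter 0 of the 30 passed over the list alone, and with a mean of at least 5 it was 12 of the 12 tested. The list passed camera with the preset correlation (adjusted p = 6.31e-38), with adjusted p = 0.644 with an estimated correlation. Nuf2, a kinetochore protein, was at 0.289 and 0.619 FPKM in DMSO and 7.27 and 14.2 FPKM in ACSS2i (log2 fold change 2.96 ± 0.37, SE). Mki67, at chromosome 7, 135689784 to 135716361 on the minus strand, had a log2 fold change of 2.87 ± 0.42 (SE). Top2a, the topoisomerase that untangles replicated chromosomes, rose from 1.71 and 4.02 to 19.6 and 44.4 FPKM (log2 fold change 3.05), and the mitotic motor Cenpe from 0.622 ± 0.232 to 4.71 ± 0.109 FPKM (SD, n = 2 each; log2 fold change 1.82).

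The S phase and replication list went the same way. All 28 members had a positive log2 fold change, 23 rose when adjusted over the list alone, 5 did not pass, and 0 passed over all genes. Fewer than the 23 passed over the list alone without DMSO replicate 1, DMSO replicate 2 or ACSS2i replicate 2, where the spread comes from the intact pair alone. In these fits 26, 28 and 27 of the 28 were positive, in that order. Without an expression filter 0 of the 28 passed, and with a mean of at least 5 it was 13 of the 18 tested. The median log2 fold change was 1.10 (0.67 with a pseudocount of 5), with list medians of 0.90 and 1.34 in the inhibitor libraries (camera with the preset correlation, adjusted p = 1.1e-22; adjusted p = 0.644 with an estimated correlation). Mcm10, a replication initiation factor, was at 1.01 and 0.91 FPKM in DMSO and 10.8 and 7.46 FPKM in ACSS2i, with the smallest unadjusted p of any gene outside short RNAs (log2 fold change 2.35 ± 0.29, SE). Rrm2, a subunit of ribonucleotide reductase, rose by a log2 fold change of 1.88, the helicase subunit Mcm5 by 2.00 and the replicative helicase component Cdc45 by 1.41. Among the 100 genes with the smallest p, 20 belonged to these 2 lists.

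**Figure D2:**
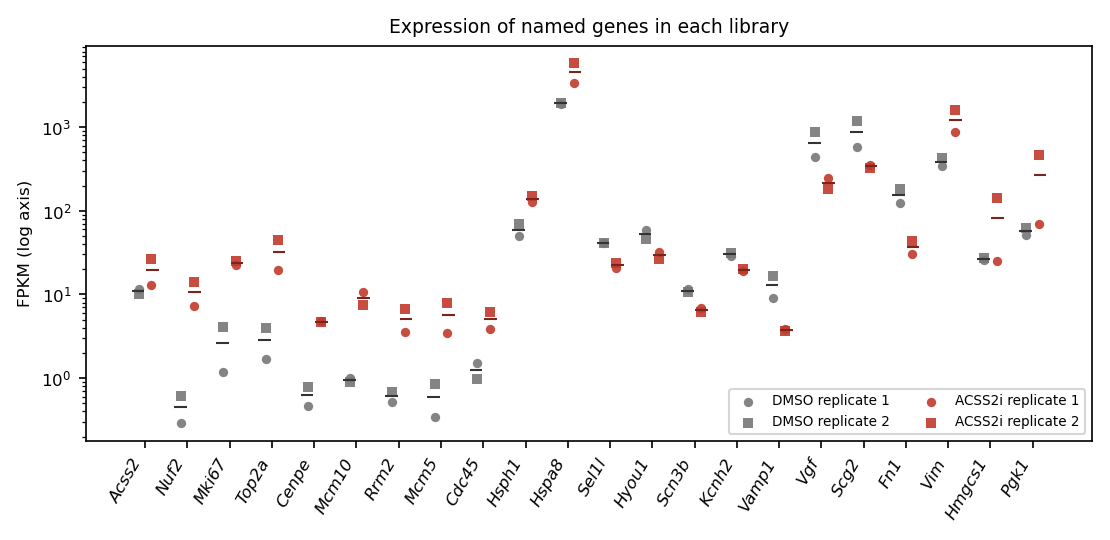
FPKM (log axis) of named genes in the DMSO libraries (grey) and the ACSS2i libraries (red), with circles for replicate 1, squares for replicate 2 and a line at the mean of each group. Mki67 lies at 1.18 and 4.13 FPKM in DMSO and at 22.2 and 24.9 FPKM in ACSS2i, and Pgk1 at 466 FPKM in ACSS2i replicate 2 and at 68.8 FPKM or less in the other libraries.

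Acss2, at chromosome 2, 155517948 to 155585724 on the plus strand, was expressed in every library, at 11.7 and 10.0 FPKM in DMSO and 12.8 and 26.6 FPKM in ACSS2i (log2 fold change 0.72 ± 0.37, SE; adjusted p = 0.785). Its paralogs fell below the expression filter: Acss1 was at the floor in DMSO and at 0.0347 and 0.0273 FPKM in ACSS2i, and Acss3 was at the floor in all 4 libraries. The list of acetyl-CoA producing enzymes and carriers was higher, with 15 of 18 members positive and a median of 0.34 (preset correlation, adjusted p = 0.00187; adjusted p = 0.644 with an estimated correlation). Despite its name, the list as fixed also holds the pyruvate dehydrogenase kinases (Pdk) and citrate synthase (Cs), which do not produce acetyl-CoA. Its shift therefore does not stand for acetyl-CoA production. Adjusted over the list alone 0 of the 18 passed, as over all genes. Hadhb and Hadha, the subunits of the mitochondrial trifunctional protein of fatty acid oxidation, had log2 fold changes of 0.74 and 0.58, the thiolase Acaa2 had 0.55 and Pdhb of pyruvate dehydrogenase 0.59. The call was lost without ACSS2i replicate 2, where the median was 0.13, and the median was 0.62 without ACSS2i replicate 1, where 5 genes passed higher over the list alone.

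Enzymes that add or remove acetyl groups on histones did not pass as groups. The histone acetyltransferases had a median of -0.0063 over 16 genes (adjusted p = 0.665), with a positive camera direction. The deacetylases and sirtuins had a median of 0.0023 over 17 genes (adjusted p = 0.693), with a negative camera direction. In both lists 0 genes passed, adjusted over the list alone or over all genes. Hat1, which acetylates newly made histones, was at 21.5 and 27.6 FPKM in DMSO and 49.8 and 52.2 FPKM in ACSS2i (log2 fold change 1.03, unadjusted p = 0.00513). Kat2b, Taf1 and Ep300 had log2 fold changes of 0.31, 0.28 and -0.29, and Sirt3, Hdac4, Sirt2 and Sirt1 of 0.60, -0.38, -0.31 and 0.42.

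The list of cytosolic heat shock genes and that of endoplasmic reticulum chaperones went in opposite directions. Despite its name, the cytosolic list as fixed also holds the mitochondrial Hspd1 and Hspe1. In the cytosolic heat shock list 13 of 15 genes were positive, with a median of 0.56 (preset correlation, adjusted p = 1.52e-05; adjusted p = 0.644 with an estimated correlation). Adjusted over the list alone 0 passed, and 0 over all genes, while 7 passed over the list alone without ACSS2i replicate 1, 3 under quantile normalization and 1 with short RNA genes left out. Hsph1 was at 49.8 and 68.7 FPKM in DMSO and 129 and 149 FPKM in ACSS2i, Hspa8, the constitutive Hsc70, went from 1917 ± 39.0 to 4559 ± 1689 FPKM, Hsp90ab1 from 2240 ± 323 to 4576 ± 1124 FPKM (SD, n = 2 each), and Hspa4l had a log2 fold change of 0.90. The size of the list's shift rested on single libraries: the median was 0.28 without ACSS2i replicate 2, 0.97 without ACSS2i replicate 1 and 0.86 without DMSO replicate 2.

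In the list of endoplasmic reticulum chaperones and the unfolded protein response 19 of 22 genes were negative, with a median of -0.57 (preset correlation, adjusted p = 8.78e-06; adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone 0 passed, and 0 over all genes. Sel1l, a subunit of the ubiquitin ligase complex of endoplasmic reticulum-associated degradation, was at 41.0 and 41.7 FPKM in DMSO and 20.7 and 23.8 FPKM in ACSS2i (log2 fold change -0.87 ± 0.22, SE). The chaperones Hyou1, Hsp90b1 and Dnajb11 had log2 fold changes of -0.81, -0.85 and -0.76. The DMSO libraries themselves stood apart on this list, at 0.31 and -0.31 from their mean, and without DMSO replicate 1 the call was lost, with a median of -0.26.

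Among neuronal genes, those of voltage-gated ion channels were lower with the inhibitor: 15 of 16 were negative, with a median of -0.50 (preset correlation, adjusted p = 0.000171; adjusted p = 0.644 with an estimated correlation). Adjusted over the list alone 0 passed, and 0 over all genes. The sodium channel subunit Scn3b was at 11.6 and 10.6 FPKM in DMSO and 6.79 and 6.24 FPKM in ACSS2i, and the potassium channel Kcnh2 went from 30.1 ± 1.69 to 19.4 ± 0.847 FPKM (SD, n = 2 each). The calcium channel Cacna1b had a log2 fold change of -0.55, with -0.95 in ACSS2i replicate 1 and -0.15 in ACSS2i replicate 2 relative to the DMSO mean. The call was lost without ACSS2i replicate 1, where the median was -0.23. The median was -0.24 with a pseudocount of 5, -0.12 without a filter and -0.25 after the length and GC correction. Without a filter 1 gene passed higher over the list alone, Cacna1e, at the floor in DMSO and at 0.0564 and 0.0518 FPKM in ACSS2i.

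The 2 lists of the synapse also passed, lower. Of the synaptic vesicle and presynaptic genes 16 of 29 were negative, with a median of -0.23 (preset correlation, adjusted p = 0.0238; adjusted p = 0.644 with an estimated correlation), and in the postsynaptic list 14 of 19, with a median of -0.31 (adjusted p = 0.02; adjusted p = 0.644 with an estimated correlation). In both lists 0 genes passed, adjusted over the list alone or over all genes. Vamp1, a vesicle fusion protein, was at 12.8 ± 5.39 FPKM in DMSO and 3.75 ± 0.139 FPKM in ACSS2i (SD, n = 2 each; log2 fold change -1.48). Nrxn2, Syt11 and Bsn had log2 fold changes of -0.74, -0.79 and -0.81, and on the postsynaptic side Nlgn2 and Chrnb2 had -0.56 and -0.52. Grin1 was at 8.48 and 11.5 FPKM in DMSO and 9.18 and 2.59 FPKM in ACSS2i. Synapsin 1 (Syn1) and synaptophysin (Syp) had log2 fold changes of 0.15 and -0.41, with unadjusted p of 0.583 and 0.117. The presynaptic call was lost without DMSO replicate 2 (median -0.26), without ACSS2i replicate 1 (-0.026), without a filter (0), with a mean of at least 5 (-0.11) and after the length and GC correction (-0.022). The postsynaptic call was lost without DMSO replicate 2 (-0.29) or either inhibitor library (-0.21 without replicate 1, -0.34 without replicate 2), and likewise without a filter (-0.016), with a mean of at least 5 (-0.30) and after the correction (-0.18). The postsynaptic median was -0.17 with a pseudocount of 5.

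The other lists of neuronal identity did not pass. For the neuronal cytoskeleton and axon growth the median was -0.13 over 30 genes (adjusted p = 0.153), for catecholaminergic and neuroendocrine genes -0.13 over 19 (adjusted p = 0.102) and for immediate early genes -0.080 over 22 (adjusted p = 0.267), and in each 0 genes passed, adjusted over the list alone or over all genes. Tubb2b, a tubulin of growing neurons, was at 69.9 and 112 FPKM in DMSO and 201 and 195 FPKM in ACSS2i, while the axonal motors Kif5c and Kif5a and the adhesion molecule L1cam had log2 fold changes of -0.91, -0.52 and -0.65. Gap43 and Map2 had -0.37 and 0.092, and Tubb3 was at 99.0 and 134 FPKM in DMSO and 121 and 323 FPKM in ACSS2i. The secreted proteins of dense core vesicles Vgf, Scg2 and Chgb had lower values in both inhibitor libraries than in both DMSO libraries: Vgf was at 652 ± 305 FPKM in DMSO and 214 ± 43.7 in ACSS2i, Scg2 at 880.5 ± 431 and 339 ± 14.8, and Chgb at 8406 ± 2269 and 3481 ± 1375 (SD, n = 2 each; unadjusted p = 0.0092, 0.0194 and 0.0314 by limma). Chga, of the same list, overlapped between groups, at 192 and 208 FPKM in DMSO and 78.1 and 228 FPKM in ACSS2i. Gch1 had a log2 fold change of 0.35 and Th, tyrosine hydroxylase, of 0.043 at 3.53 and 3.16 FPKM in DMSO and 4.09 and 2.92 in ACSS2i. Dbh was below the filter, at 0.344, 0.524, 0.226 and 0.624 FPKM. The immediate early gene Egr1 was at 27.2 and 54.0 FPKM in DMSO and 5.57 and 20.9 FPKM in ACSS2i (log2 fold change -1.71, unadjusted p = 0.0316). Btg2, Klf10 and Dusp6 had -0.61, 0.65 and -1.11, and Fos was below the filter at 0.546, 1.30, 0.187 and 0.392 FPKM. The groups overlapped for Dusp6, at 70.2 and 144 FPKM in DMSO and 28.6 and 74.3 FPKM in ACSS2i. Each of these 3 lists passed, lower, without DMSO replicate 1, with medians of -0.16, -0.34 and -0.26, and the catecholaminergic list also without ACSS2i replicate 2 (-0.37). Over the 4 libraries their adjusted p with an estimated correlation was 0.695, 0.695 and 0.765. Without ACSS2i replicate 2, 5 catecholaminergic genes (Ddc, Slc18a2, Hand2, Gata2 and Chga) and 2 immediate early genes (Egr1 and Ier3) passed lower over the list alone.

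Of 11 tested neural progenitor and Notch genes, 1 rose and 1 fell when adjusted over the list alone, 9 did not pass, and 0 passed over all genes. Over the list alone 0 passed without DMSO replicate 1, 0 without DMSO replicate 2, 0 without ACSS2i replicate 2 and 0 without a filter, so that Vim and Id4 lost their calls there, and 2 passed higher and 1 lower without ACSS2i replicate 1. Vim, the intermediate filament vimentin, rose from 381 ± 61.1 to 1228 ± 506 FPKM (SD, n = 2 each; log2 fold change 1.63), and Id4, an inhibitor of basic helix-loop-helix factors, fell from 35.7 and 28.5 to 13.3 and 8.15 FPKM (log2 fold change -1.52). Msi1 and Hes6 had log2 fold changes of -0.35 and 0.55. The list itself had a median of -0.16 (adjusted p = 0.665).

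Lists of central metabolism were higher with the inhibitor, and most of the shift lay in ACSS2i replicate 2. For cholesterol biosynthesis and SREBP2 targets the median was 0.69, with 20 of 24 genes positive (preset correlation, adjusted p = 0.000642; adjusted p = 0.695 with an estimated correlation). The glycolysis and hypoxia list had a median of 0.79, with 25 of 26 positive (adjusted p = 0.000168; adjusted p = 0.695 with an estimated correlation). In ACSS2i replicate 1 the medians of these 2 lists were -0.12 and -0.080, and in ACSS2i replicate 2 they were 1.55 and 1.57, so that both lists lost the call and turned direction without ACSS2i replicate 2. Adjusted over the list alone 0 genes of either passed, and 0 over all genes. Without ACSS2i replicate 1, 19 cholesterol genes and 23 glycolysis genes passed higher over the list alone, and 1 glycolysis gene, Vegfa, lower. Hmgcs1, the enzyme ahead of HMG-CoA reductase in sterol synthesis, was at 26.0 and 27.4 FPKM in DMSO and 25.3 and 141 FPKM in ACSS2i. Farnesyl diphosphate synthase (Fdps) was at 44.1, 51.6, 55.6 and 317 FPKM in the same order, and Fdft1, Nsdhl and Acat2 had log2 fold changes of 1.24, 1.47 and 1.20. For Acat2 the groups overlapped. Phosphoglycerate kinase (Pgk1) was at 51.2, 62.4, 68.8 and 466 FPKM, Gpi1 and Hk2 had log2 fold changes of 0.84 and 0.78, and Vegfa, a hypoxia-induced growth factor, had -0.84 at 312 and 296 FPKM in DMSO and 169.2 and 169.4 FPKM in ACSS2i.

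**Figure D3:**
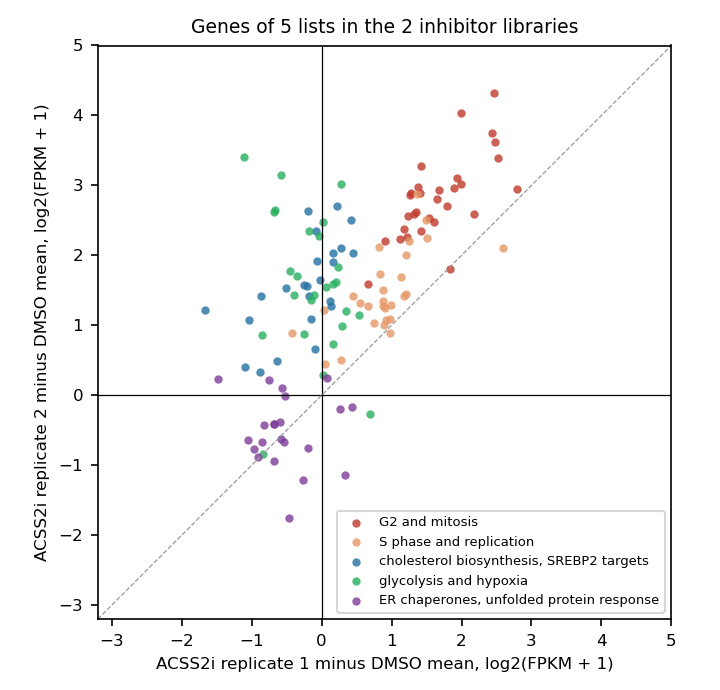
Each point is a gene of 1 of 5 lists, with its log2(FPKM + 1) minus the DMSO mean in ACSS2i replicate 1 (horizontal axis) and in ACSS2i replicate 2 (vertical axis); the dashed line marks equal values. Genes of G2 and mitosis lie above 0 on both axes, with medians of 1.57 and 2.84, while cholesterol and glycolysis genes are spread around 0 on the horizontal axis and have medians of 1.55 and 1.57 on the vertical one.

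The mitochondrial lists shared this dependence. For the tricarboxylic acid cycle all 20 genes were positive, with a median of 0.35 (preset correlation, adjusted p = 2.25e-05; adjusted p = 0.688 with an estimated correlation), and for nuclear oxidative phosphorylation 33 of 39, with a median of 0.28 (adjusted p = 0.000287; adjusted p = 0.695 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.18, with 36 of 40 positive (adjusted p = 0.0238; adjusted p = 0.765 with an estimated correlation). In all 3 lists 0 genes passed, adjusted over the list alone or over all genes. Fumarase (Fh1), Idh2, Sdha and pyruvate carboxylase (Pcx) had log2 fold changes of 0.76, 0.74, 0.65 and 0.85, and Ndufs1, Atp5a1 and Ndufa9 of the respiratory chain and ATP synthase had 0.54, 0.63 and 0.54. Rps2, Rpl22, Rps4x and Rpl7 had 0.51, 0.46, 0.45 and 0.39. Without ACSS2i replicate 2 all 3 calls were lost, with medians of 0.14, 0.042 and -0.031, and without ACSS2i replicate 1 the medians were 0.58, 0.53 and 0.41, with 4 genes of the tricarboxylic acid cycle higher over the list alone. The oxidative phosphorylation and ribosomal calls were also lost without DMSO replicate 2 (0.16 and 0.097) and had medians of 0.42 and 0.27 without DMSO replicate 1, while the ribosomal call was further lost under quantile normalization (0.027) and the length and GC correction (0.12). Fatty acid synthesis genes had a median of 0.010 over 16 genes, with a negative mean of -0.095 and a negative camera direction (adjusted p = 0.665), and 0 passed, adjusted over the list alone or over all genes. The list passed lower without ACSS2i replicate 2 (median -0.50, with 3 genes lower over the list alone) and higher without ACSS2i replicate 1 (0.49), with adjusted p = 0.894 over the 4 libraries with an estimated correlation. Acsl4, an arachidonate-activating enzyme, was at 95.1 and 161 FPKM in DMSO and 36.6 and 61.6 FPKM in ACSS2i, and Srebf1, Mcat and Acsl3 had log2 fold changes of -0.75, 0.27 and -0.31. For Srebf1 and Acsl3 the groups overlapped.

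Replication-dependent histone genes were lower, with 7 of 8 tested members negative and a median of -0.75 (preset correlation, adjusted p = 0.0222; adjusted p = 0.695 with an estimated correlation). The NRF2 targets had 15 of 21 genes negative and a median of -0.12 (adjusted p = 0.0459; adjusted p = 0.695 with an estimated correlation). In both lists 0 genes passed, adjusted over the list alone or over all genes. The linker histones Hist1h1c, Hist1h1d and Hist1h1e had log2 fold changes of -1.11, -1.16 and -1.08, and Hist2h2be -0.47. The histone list lay at -0.092 in ACSS2i replicate 1 and -1.70 in ACSS2i replicate 2, and without ACSS2i replicate 1 there were 4 genes lower over the list alone. Its call was lost without ACSS2i replicate 2 (median -0.092), without DMSO replicate 1 (-0.62) and without a filter (-0.20). The quinone reductase Nqo1 was at 2.65 and 6.27 FPKM in DMSO and 1.92 and 1.10 FPKM in ACSS2i, ferritin heavy chain (Fth1) had a log2 fold change of -0.79, Txnrd1 -0.77 and Tkt 0.74. The NRF2 call was lost without DMSO replicate 2 (-0.13), without ACSS2i replicate 2 (-0.037), with a pseudocount of 0.1 (-0.12), without a filter (-0.11) and with a mean of at least 5 (-0.10). The median was -0.55 without ACSS2i replicate 1, -0.25 without DMSO replicate 1, -0.27 under quantile normalization and -0.25 after the length and GC correction.

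The remaining stress and signalling lists did not pass, and in each 0 genes passed, adjusted over the list alone or over all genes. The interferon response list had a median of -0.37 over 12 genes (adjusted p = 0.0539). Isg15, a ubiquitin-like interferon product, was at 41.2 and 266 FPKM in DMSO and 14.8 and 4.55 FPKM in ACSS2i, and Ifit1, Oasl2 and Oasl1 had log2 fold changes of -1.71, -1.02 and -0.95. This list passed without DMSO replicate 1 (-0.32), with short RNA genes left out (-0.37) and after the length and GC correction (-0.43), and its median turned to 0.036 without ACSS2i replicate 1. With an estimated correlation its adjusted p over the 4 libraries was 0.644, and by fry 0.508. Isg15, Ifit1 and Oasl1 passed lower over the list alone without DMSO replicate 1. The p53 targets had a median of 0.011 over 16 genes, with a mean of -0.13 and a negative camera direction (adjusted p = 0.255). ATF4 and amino acid response genes had a median of 0.021 over 30, also with a negative camera direction (adjusted p = 0.693), and lysosome and autophagy genes -0.026 over 32 (adjusted p = 0.223). Gdf15, a stress-induced cytokine that stands in both the p53 and the ATF4 list, was at 37.7 and 44.3 FPKM in DMSO and 15.9 and 20.0 FPKM in ACSS2i (log2 fold change -1.15 ± 0.24, SE). Over the p53 list alone Gdf15 passed with a mean of at least 5, under quantile normalization, with short RNA genes left out and without ACSS2i replicate 2, where 1 other gene passed higher. Sesn2 and Bbc3 had log2 fold changes of -0.42 and -0.39, the cell cycle inhibitor Cdkn1a 0.069, and Slc6a9, Slc7a11 and Asns -1.12, -1.20 and 0.60. For Slc7a11 the groups overlapped, at 10.5 and 35.7 FPKM in DMSO and 11.5 and 5.41 FPKM in ACSS2i. Lamp2, Ctsd, Ctsf and Atp6v0d1 had log2 fold changes of -0.87, -1.21, -0.85 and 0.72. The lysosome list passed, lower, without ACSS2i replicate 1 (-0.40), with adjusted p = 0.765 over the 4 libraries with an estimated correlation. Of the aryl hydrocarbon receptor targets 4 were tested, too few for the list test, and 0 passed, adjusted over the list alone or over all genes: Nqo1 at the values above, and Hspb2, Nfe2l2 and Tiparp with log2 fold changes of -0.82, -0.39 and 0.020.

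Markers of other cell types were scarce. Of 17 glial markers 4 were tested (among them Pmp22 at -1.01, Cnp at -0.23 and Mbp at 0.10 on the log2 scale), and 0 passed, adjusted over the list alone or over all genes, with Pmp22 lower over the list alone without ACSS2i replicate 2. For Pmp22 the groups overlapped, at 156 and 250 FPKM in DMSO and 58.2 and 162 FPKM in ACSS2i. Of 17 fibroblast and matrix markers 3 were tested, and of 13 immune cell markers 0. Fibronectin (Fn1), at chromosome 1, 71585520 to 71653200 on the minus strand, fell from 153 ± 43.7 to 37.1 ± 9.85 FPKM (SD, n = 2 each; log2 fold change -2.01). It was the 1 fibroblast marker that passed adjusted over the list alone, and 0 passed over all genes. Without a filter 0 passed over the list alone, and 2 passed without ACSS2i replicate 1 (with Pdgfrb) or without ACSS2i replicate 2 (with Sparc). Pdgfrb and Sparc had log2 fold changes of -0.75 and -0.64.

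The 3 genes that passed over all genes are short, and each was at the floor in both libraries of 1 group, so that no fold is given. Snora64, a small nucleolar RNA within the Rps2 locus (chromosome 17, 24720772 to 24720905, plus strand), was at 49.3 and 77.7 FPKM in ACSS2i (limma, adjusted p = 0.0106). Snora16a, within the host gene Snhg12 (chromosome 4, 132309464 to 132309600, plus strand), was at 23.2 and 36.5 FPKM in ACSS2i (adjusted p = 0.02). Both overlap an exon of some annotated transcript of their host. Any transcript was counted, so this does not place them in exons of the main host transcript. Mir7063, in an intron of Ap2a2 (chromosome 7, 141620701 to 141620791, plus strand), was at 168 and 575 FPKM in DMSO (adjusted p = 0.0233). The libraries were made from polyadenylated RNA, so these values may not measure the mature small RNAs. They cannot tell reads of these genes from reads of the host transcripts that overlap them. After scaling by relative depth the values above the floor stood in whole ratios of 1 to 2, 1 to 2 and 1 to 1. The number of genes called was 26 without DMSO replicate 1, 21 without DMSO replicate 2, 13 without ACSS2i replicate 1 and 16 without ACSS2i replicate 2, and Mir7063 was not among them without either inhibitor library. The number was 0 with short RNA genes left out, with 834 genes at an unadjusted p under 0.05.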

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

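Of the settings below, the omission of short RNA genes and the length and GC correction were chosen after the data had been seen, and the others before. The 3 called genes were called again under median-of-ratios scaling, quantile normalization, and the moderated test without a trend or in its robust form. The count of called genes was 2 with a mean of at least 5, 2 after the length and GC correction and 6 with a pseudocount of 0.1, all short RNA genes. It was 0 with a pseudocount of 5 (795 genes at an unadjusted p under 0.05), 0 with no filter (1342 genes, over more genes tested) and 0 with short RNA genes left out (834 genes), where the omission itself removes the 3. With each library left out in turn it ranged from 13 to 26; the lone library of a group is then assumed to vary like the pair of the other group. With the replicate number as a block it was 8, 6 of them short RNA genes and the others Top2a and Birc5. The labels do not say whether same-numbered libraries share a day or a culture. Their deviations correlated at -0.02 across genes (0.04 without short RNA genes), which cannot settle it. The number of lists called ranged from 8 to 17 with a library left out, was 17 under the replicate block (the interferon and catecholaminergic lists joined the 15; Egr1 also passed lower over its list alone), and was 0 with an estimated correlation and 0 by fry. The G2 and mitosis list (2.16) and the S phase list (1.10) keep their medians under both tests, since only the test differs, and lost the call there. They kept it in the other settings listed here, with medians of 1.57 to 2.84 and 0.90 to 1.34 over the left-out libraries. Without a filter 0 of their genes passed over the list alone, and the cause was not tested. With a pseudocount of 5 the medians were 1.00 and 0.67, and with one of 0.1 the G2 and mitosis median was 3.35, since the pseudocount sets how far low values spread.

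Some lists changed direction, as camera gives it, in at least 1 of the fits that left out a library, and the cause was not tested beyond which library was left out. Their medians ranged from -0.15 to 0.24 (histone acetyltransferases), -0.19 to 0.094 (deacetylases), -0.12 to 1.55 (cholesterol biosynthesis), -0.50 to 0.49 (fatty acid synthesis), -0.26 to 0.12 (immediate early genes), -0.37 to 0.12 (catecholaminergic genes), -0.16 to 0.16 (neural progenitor genes), -0.22 to 0.18 (ATF4 response), -0.080 to 1.57 (glycolysis), -0.40 to 0.094 (lysosome) and -0.031 to 0.41 (ribosomal proteins). The median alone changed sign for the neuronal cytoskeleton (-0.30 to 0.078), p53 targets (-0.21 to 0.042) and the interferon response (-0.60 to 0.036). Fatty acid synthesis also turned, by its camera direction, with no filter (0.039). Of 123 named genes 68 moved by over 1.5 times or changed sign with a library left out, and the groups overlapped in 21. A total of 13 changed sign in at least 1 setting, and none of these 13 passed the test over all genes. Their log2 fold changes with a library left out ranged from -0.014 to 0.85 (Sirt1), -1.57 to 0.066 (Srebf1), -0.85 to 0.23 (Acsl3), -0.092 to 1.20 (Hes6), -0.19 to 0.23 (Tiparp), -0.64 to 0.18 (Cnp), -0.063 to 0.27 (Mbp), -0.084 to 0.38 (Syn1), -0.90 to 0.15 (Gap43), -0.20 to 0.39 (Map2), -0.15 to 0.23 (Th), -0.075 to 2.35 (Hmgcs1) and -0.65 to 0.79 (Cdkn1a). After the length and GC correction Tiparp was at -0.044 and Th at -0.0098. Apart from left-out libraries and the other list tests, the lists other than those of the cell cycle that lost their call numbered 4 with no filter, 3 with a mean of at least 5 (where the histone list had too few genes to be tested), 3 after the length and GC correction, 1 with a pseudocount of 0.1 and 1 under quantile normalization. A test on counts was not run, because whole reads were not recovered for all genes. Depth limits low genes most in DMSO replicate 2, where 1 read in a transcript of 3 kb is worth 0.0988 FPKM.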

Other observations

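Of the tests in this part, those of GC content and transcript length were written down before their results were seen, and all others, with the gene families below, were chosen after the data had been examined. All 11 tested collagen genes had a negative log2 fold change, with a median of -0.65 and values from -1.24 to -0.058 (Col4a1), among them Col11a2 at 10.1 and 4.58 FPKM in DMSO and 2.41 and 2.24 FPKM in ACSS2i. The 3 laminin genes were negative (median -1.25), with Lama4 at 72.5 and 29.3 FPKM in DMSO and 12.5 and 4.67 FPKM in ACSS2i. Of 10 semaphorins, which guide axons, 9 were negative (median -0.57), with Sema3f at 4.08 and 4.78 FPKM in DMSO and 1.25 and 0.755 FPKM in ACSS2i. The granins and their relatives of the dense core vesicle were negative in 8 of 8 genes (median -0.93, with Scg3, Scg5 and Ptprn2 at -0.12, -0.13 and -0.17), a group that holds members of the catecholaminergic list; Ptprn, a membrane protein of these vesicles, was at 106 and 104 FPKM in DMSO and 30.6 and 46.9 FPKM in ACSS2i. With a library left out these medians ranged from -0.97 to -0.51 for collagens, -1.31 to -1.20 for laminins, -0.67 to -0.46 for semaphorins and -1.07 to -0.64 for granins. For collagens the median was -0.31 with a pseudocount of 5 and -0.27 over the 4 genes with a mean of at least 5, and 2 turned positive without DMSO replicate 2, without ACSS2i replicate 1 and after the length and GC correction. For laminins it was -0.57 with a pseudocount of 5, and 1 of the 3 was positive without DMSO replicate 2. Of the 8 granins 3 were positive without ACSS2i replicate 1 and 1 without DMSO replicate 2, and of the 10 semaphorins 2 after the length and GC correction. Not all genes of these families were lower in both inhibitor libraries. Col4a1, Col4a2, Sema4g, Chga and Scg5, among others, were higher in ACSS2i replicate 2 than in at least DMSO replicate 1. The 3 tested fibroblast and matrix markers, Fn1, Pdgfrb and Sparc, had lower values in both inhibitor libraries, at -2.01, -0.75 and -0.64. Sparc was nearly level in ACSS2i replicate 2, at 4.20 and 4.25 FPKM in DMSO and 1.21 and 4.11 FPKM in ACSS2i.

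Among families with higher values, all 12 tested genes named Ncap or Smc were positive (median 0.55). This group is called condensin and cohesin below, but it also holds Smc5 (0.15) and Smc6 (0.23), which belong to neither complex. Positive too were all 7 tested subunits of the cytosolic chaperonin (median 0.57), 17 of 20 nucleoporins (median 0.33) and 32 of 37 proteasome subunits (median 0.23). The same held for 61 of 76 mitochondrial ribosomal proteins (median 0.15) and 6 of 7 Fanconi anemia genes (median 0.35). The 2 latent TGF-beta binding proteins were negative (median -1.15), as were 14 of 17 genes of glycan assembly (median -0.24). With a library left out these medians ranged from 0.46 to 0.84 for condensin and cohesin, with the highest without DMSO replicate 2, and from 0.24 to 0.37 for nucleoporins. The chaperonin was at 0.29 without ACSS2i replicate 2 and 0.86 without ACSS2i replicate 1, the mitochondrial ribosomal proteins at 0.092 and 0.26, and the Fanconi anemia genes at 0.21 and 0.11. Glycan assembly was at -0.14 without DMSO replicate 1 and -0.36 without DMSO replicate 2. Condensin and cohesin were at 0.31 with a mean of at least 5, Fanconi anemia genes at 0.15 with a pseudocount of 5 and at 0.063 for the 1 gene left with a mean of at least 5, and mitochondrial ribosomal proteins at 0.091 after the length and GC correction. All 12 families examined are given here, and p-values are adjusted over the 12. The laminins and the latent TGF-beta binding proteins, with 3 and 2 tested genes, had fewer than the 5 asked of the fixed lists, and no p is given for them. Camera with the preset correlation gave adjusted p of 4.77e-07 for condensin and cohesin, 8.94e-05 for collagens, 0.000121 for both semaphorins and granins, 0.00029 for the chaperonin, 0.00113 for nucleoporins, 0.00155 for the proteasome, 0.00223 for mitochondrial ribosomal proteins, 0.0184 for glycan assembly and 0.0421 for Fanconi anemia genes. With an estimated correlation the adjusted p was 0.171 for condensin and cohesin, semaphorins, granins and nucleoporins. It was 0.199 for collagens, 0.257 for Fanconi anemia genes, 0.358 for the chaperonin, 0.386 for glycan assembly, 0.416 for mitochondrial ribosomal proteins and 0.496 for the proteasome. These families were picked from genes with small p, so their p-values are too small. The median of the proteasome turned to -0.015 without ACSS2i replicate 2 and was 0.44 without ACSS2i replicate 1, 0.15 without DMSO replicate 1, 0.14 under quantile normalization and 0.13 after the length and GC correction, and no other family changed the sign of its median in any setting.

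The first pattern is the higher level of division genes with the inhibitor. A correction for length and GC content left the median of the 30 G2 and mitosis genes at 2.10, the median was 2.25 without the shallow DMSO replicate 2, and it was 1.57 or more without either inhibitor library, all of which argue against those explanations as the whole cause. A higher share of cycling cells in the inhibitor cultures stays open: of 37 genes of the Cenp, Ncap, Ska, Fanc, Orc and Prim name families outside the fixed lists 33 (89.2%) were positive, but these division genes were chosen after the pattern was seen and restate it. The replication-dependent histones decide nothing here, since their transcripts mostly lack a poly(A) tail and their median was -0.092 in ACSS2i replicate 1 and -1.70 in ACSS2i replicate 2. A chance difference between pairs of cultures cannot be told apart from an effect of the inhibitor, since camera with an estimated correlation gave an unadjusted p = 0.0967. In simulated lists that test found no shift of log2 1 at an adjusted p under 0.05. The simulations held no shift as large as the median of 2.16 and no correlation as high as the 0.838 estimated for this list. They therefore do not give the power of the test for it.

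The second pattern is the level of cholesterol and glycolysis genes in ACSS2i replicate 2, higher than in ACSS2i replicate 1 in 49 of 50 genes, with a median difference of 1.72 on the log2 scale. Scaling of a whole library is argued against by a median difference of 0.022 over all tested genes, and length and GC content by a median of 1.69 for the 50 genes after the correction. A difference between the cultures apart from the inhibitor may account for the pattern and cannot be told apart from a variable response to it, because the labels give no condition of single cultures. The same genes differed by a median of 0.25 between the DMSO libraries.

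The third pattern is the call of short RNA genes alone. Single reads in short genes are a candidate source of these calls, which the values cannot settle. The values above the floor stood in whole ratios of at most 2 in 3 of the 3 genes once scaled by relative depth. Such a ratio fixes no number of reads. An FPKM value divides by length, so 1 read is worth more in a shorter transcript. At the nominal depths, division by the full annotated lengths of 134, 137 and 91 bp would leave 1 read far below the values seen. The length that Cufflinks divided by is not given in the sources used here, so this division does not argue against single reads. The lowest of these was 23.2 FPKM, and how many reads they stand for was not worked out. Both libraries of the other group held the floor. No biological explanation was tested for these genes.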
